A study of Mus musculus with 6 samples.

How the data were processed

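Treg were sorted by flow cytometry from the spleen of C57BL/6 mice, and libraries were made with SmartSeq2 and sequenced on an Illumina HiSeq, per the labels' protocols. FastQC, cutadapt and HISAT2 are named in the submitters' processing notes, with the mouse builds NCBIM37 and mm9 and no versions. The FPKM values (fragment numbers scaled for transcript length and library size) were deposited by the authors as a table of 36811 genes by 6 libraries, and the table's name gives cuffnorm as their source. The annotation, strand setting and any filter are not given in the sources used here. The series' design text speaks of Treg with high and low Bach2 from reporter mice. Such libraries were not analysed here, and groups were taken from the sample labels.

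Ensembl gene identifiers were matched to symbols through the reference tables, and 31840 of 36811 matched. The list genes Hbb-b1, Hbb-b2, Hmgcs1, Bcl2a1d and Igha found no match, and the same unrelated row without a symbol was put in their place. That row was not tested in the main fit but entered their lists with no filter. Among the genes tested, 513 had no symbol. Transcript length and GC content came from GENCODE M21 on GRCm38, a later build than that of the values, so no coordinates are given. FPKM sums lay between 1502820 and 1940810, and the 4 highest rows, short RNAs, took 32.4% to 46.9% of a library's sum. In 58 rows a median above 20 FPKM came with a value of 0 in some library, so a 0 is given only as listed.

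The scale from fragments to FPKM, called depth here, was estimated from low values. In 1369 of 2372 low genes with a single transcript (57.7%), the values of each library were whole multiples of a library's step within a tolerance of 0.02, against at most 9 genes in 20 draws with shifted steps. The median over 154 genes with a transcript of at least 2000 bases set the scale. Depth is therefore an estimate of that scale and need not be the number of fragments sequenced, and short transcripts move in large steps. No test on counts was run, since whole reads were not recovered for most genes.

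Genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a variance trend and no block, and p-values were adjusted by Benjamini-Hochberg at a threshold of 0.05. A fold from this scale understates the change of low genes. Folds given in the text are ratios of mean FPKM, and log2 differences are from the fit. Gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether a list's genes move one way on balance. The p-values were adjusted over the 21 of 22 lists with at least 3 tested members. The list of sex-linked transcripts had fewer. Only the effector Treg list passed with fry (adjusted p = 0.0438), and no list passed with an estimated correlation. Some genes belong to more than 1 list. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 handled tables and figures.

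The design, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule took genes past the threshold whose groups do not overlap, up to 12 in each direction, without predicted genes, small RNAs and V segments. It added Bach2, Foxp3 and up to 4 members of each list with the smallest p. Not all of these are printed, 1 of them is not reported here, and the members named in a count of a list are given by name alone. Alternatives were pseudocounts of 0.1 and 5, no filter and a minimum of 5 FPKM, quantile, equal-sum and trimmed-mean scaling, no variance trend, a robust trend, library quality weights, a replicate block, and each library left out. A restriction to protein-coding genes with a transcript of at least 300 bases, a length and GC correction, and the alternatives for the count within the effector Treg list were added after seeing the data.

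The procedure was tested on simulated data for cKO against WT with 11979 genes, 200 of them changed. The changed genes were drawn only from those above a level higher than the filter, and the folds were on the FPKM + 1 scale. The procedure recovered 16.8% of 2-fold changes, with 7.02% of calls false, and 92.0% of 4-fold changes, with 5.70% false, as means of 10 simulations. A shift of 0.5 (log2) in a list was called in 10 of 10 simulations, and 0 of 180 unshifted lists were called. The simulation has independent genes, so it does not test the preset correlation. With 3 libraries against 3 the splits number 10, and the smallest share any result can reach is 0.1. Pairwise correlations of libraries lay between 0.881 and 0.915. The libraries did not group by label. The mean correlation of cKO 1, cKO 3 and WT 3 was higher with the other group than with their own (0.909 against 0.904, 0.911 against 0.909, and 0.911 against 0.907), and the first principal component, 26.5% of the variance, set cKO 2 against WT 2.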

Results

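Gene expression was measured by RNA sequencing in regulatory T cells (Treg) of the mouse spleen. The cells were sorted by the EGFP reporter placed at Foxp3, the gene of the transcription factor that defines Treg. There were 6 libraries, 3 labelled cKO and 3 labelled WT, from C57BL/6 mice aged 18 to 21 weeks. The cKO label stands for mice with floxed Bach2 alleles and the WT label for mice with unaltered Bach2. Both carried the Cre-ERT2 recombinase at Foxp3. Bach2 encodes a transcriptional repressor, and the comparison addresses what its loss in Treg does to the transcriptome. The number of fragments sequenced is not given. The steps between low FPKM values set the scale from fragments to FPKM. It stood at about 3600000, 5010000 and 3950000 fragments in cKO 1, 2 and 3 and at about 4510000, 3030000 and 3950000 in WT 1, 2 and 3. This scale need not equal the number sequenced, as the steps of cKO 3 and WT 3 had the same weight. The labels do not say that the libraries of a group come from separate animals, so p-values measure the spread between these libraries.

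The targeted gene was not lower in the libraries labelled cKO. Bach2 (ENSMUSG00000040270) stood at 7.88, 9.19 and 6.44 FPKM in cKO 1, 2 and 3 and at 3.29, 8.25 and 4.80 FPKM in WT 1, 2 and 3. The log2 difference was 0.52 with a standard error of 0.315 and a 95% interval from -0.24 to 1.27 (limma, Benjamini-Hochberg adjusted p = 0.925). Between 132 and 409 fragments lay behind each Bach2 value by the estimated depth. The values cover the whole gene, and the deleted part of Bach2 and the tamoxifen treatment that Cre-ERT2 needs are not given in the sources used here. The Bach2 values therefore leave the labels unchecked, and each direction given for the libraries labelled cKO rests on the labels alone. Foxp3 (ENSMUSG00000039521) stood at 6.59, 9.44 and 5.75 FPKM in the libraries labelled cKO and at 7.004, 5.16 and 7.51 FPKM in those labelled WT, a log2 difference of 0.12 (limma, adjusted p = 0.976). It was -0.065 without cKO replicate 2 and -0.024 without WT replicate 2.

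Igfbp4, which encodes a binding protein of insulin-like growth factors and is found in naive T cells, was the clearest change. It stood at 82.1 ± 8.78 FPKM (SD, n = 3) in the libraries labelled cKO and at 303 ± 9.55 FPKM (SD, n = 3) in those labelled WT, 3.69-fold lower. The log2 difference was -1.88 with a standard error of 0.126 (limma, Benjamini-Hochberg adjusted p = 0.00929). Of 11979 genes tested, 3 passed an adjusted p of 0.05, with 1 higher and 2 lower in the libraries labelled cKO. The other two lie on short rows listed at 0 in a whole group. Trbj2-1, a joining segment of the T cell receptor beta chain, was listed at 0 in WT 1, 2 and 3 and at 1926, 1384 and 4386 FPKM in cKO 1, 2 and 3 (limma, adjusted p = 0.000462). Those values correspond to no fewer than 2, 2 and 5 fragments. Gm11631 was listed at 0 in cKO 1, 2 and 3 and at 15.6, 23.2 and 17.8 FPKM in WT 1, 2 and 3 (limma, adjusted p = 0.00343), values that correspond to no fewer than 1 fragment in each of these. It falls outside the naming rule and was chosen after its values were seen. At an unadjusted p under 0.05 there were 430 genes higher and 213 lower, 5.37% of those tested. This split was 770 higher and 100 lower with libraries scaled to equal sums, 341 and 277 after quantile normalization, and 359 and 276 with trimmed-mean scaling. Equal sums moved the median log2 difference of all genes from 0.03 to 0.16. The groups did not overlap in 834 genes higher and 449 lower, 10.7% of the genes against 10% given by chance. Igfbp4 no longer passed with equal sums (limma, adjusted p = 0.158), without the variance trend (0.0567), without WT replicate 1 (0.0570) or without WT replicate 3 (0.0515). Its log2 difference stayed between -1.99 and -1.71 in the 19 alternatives.

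**Figure D1:**
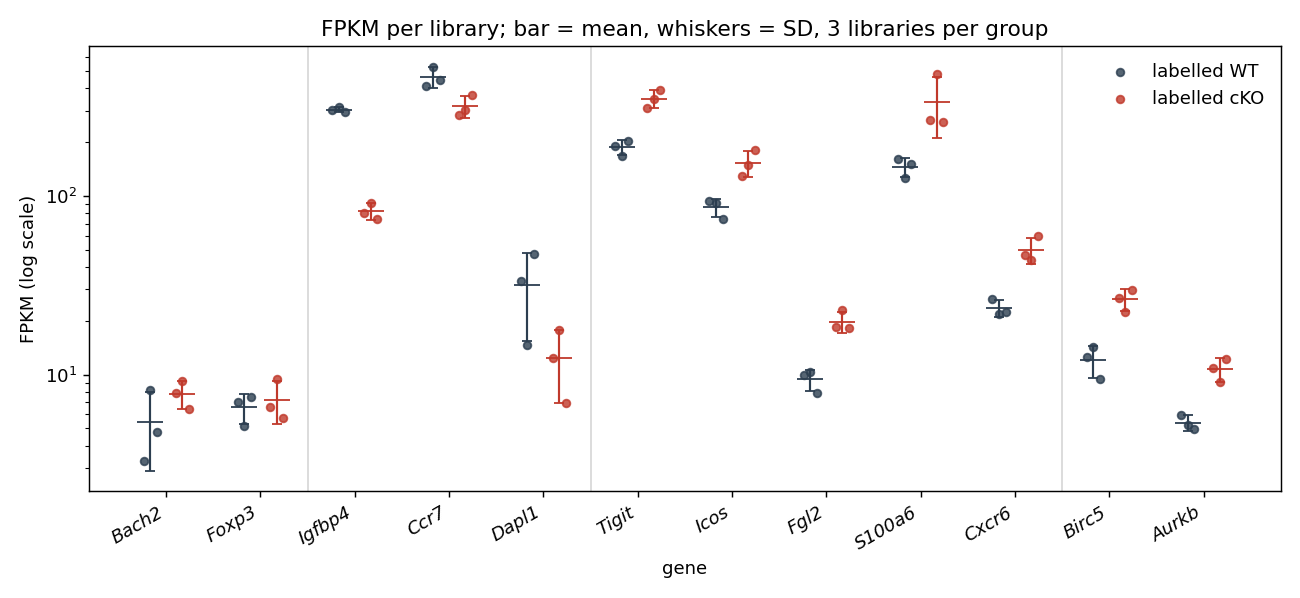
FPKM of 12 genes on a log axis in the 3 libraries labelled WT (dark) and the 3 labelled cKO (red). Points are libraries, the horizontal bar is the mean and the whiskers are the SD. Igfbp4 lies at 74.1 to 91.5 FPKM in the libraries labelled cKO and at 294 to 313 FPKM in those labelled WT, while Bach2 overlaps between the groups.

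Genes of activated, effector Treg were higher as a group in the libraries labelled cKO. Of 32 tested members of the effector Treg list, 30 had a value above 0, and the median log2 difference was 0.52 (limma camera, Benjamini-Hochberg adjusted p = 4.53e-15). The list had an adjusted p = 0.187 with an estimated correlation. No member passed over all genes tested, and 17 were higher adjusted over the list alone, with 17 members whose groups did not overlap. The 17 were Klrg1, Icos, Prdm1, Il10, Tigit, Ebi3, Tnfrsf9, Fgl2, S100a4, S100a6, Havcr2, Rora, Id2, Lgals1, Lgals3, Ccr2 and Cxcr3. Tigit, an inhibitory receptor, stood at 350 ± 40.1 against 187 ± 17.8 FPKM (SD, n = 3 each), a log2 difference of 0.90. Fgl2, a secreted suppressive mediator, stood at 19.8 ± 2.71 against 9.40 ± 1.28 FPKM, a difference of 1.0. Icos, a costimulatory receptor, stood at 153 ± 25.8 against 86.1 ± 10.2 FPKM, a difference of 0.81. S100a6, a calcium-binding protein, stood at 335 ± 125 against 146 ± 17.9 FPKM, a difference of 1.14, with its highest value of 479 FPKM in cKO 2. The count of 17 fell to 10 after quantile normalization, 11 after a length and GC correction added after the data were seen, 6 without cKO replicate 3, 4 without WT replicate 1, 6 without WT replicate 2 and 1 without WT replicate 3.

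Genes of resting Treg and of homing to lymphoid organs were lower as a group. Of 20 tested members, 5 had a value above 0. The median log2 difference was -0.12 and the mean -0.22 (limma camera, adjusted p = 9.75e-04), with an adjusted p = 0.408 with an estimated correlation. Igfbp4 passed both over all genes and adjusted over the list alone, where 1 member was lower. With its log2 difference of -1.88 Igfbp4 pulls the list's mean down, and the list was not tested without it. Ccr7, the chemokine receptor for lymphoid tissue, stood at 318 ± 44.5 against 463 ± 59.9 FPKM, a log2 difference of -0.54. Dapl1 stood at 12.4 ± 5.46 against 31.8 ± 16.3 FPKM, a difference of -1.24. Ccr7 and Dapl1 did not pass. The list's median was 0.03 with equal sums, where the test stayed downward relative to other genes (adjusted p = 0.0169), and its call ended with library quality weights (0.0535) and without cKO replicate 1 (0.126). The median was -0.041 with those weights, -0.18 after quantile normalization, -0.0080 without cKO replicate 1, -0.18 without cKO replicate 3 and -0.19 without WT replicate 1.

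Cell cycle genes were higher as a group. Of 29 tested members, 28 had a value above 0, with a median log2 difference of 0.44 (limma camera, adjusted p = 3.51e-09) and an adjusted p = 0.504 with an estimated correlation. No member passed over all genes, and 2 were higher adjusted over the list alone. These were Birc5, a chromosomal passenger protein, at 26.4 ± 3.65 against 12.04 ± 2.44 FPKM and a log2 difference of 1.08, and Aurkb, its partner kinase, at 10.7 ± 1.62 against 5.39 ± 0.522 FPKM and a difference of 0.87. Ccnb1, a mitotic cyclin, stood at 6.38 ± 0.870 against 2.48 ± 1.0 FPKM and Ube2c, a ubiquitin-conjugating enzyme of mitosis, at 16.0 ± 2.57 against 7.70 ± 2.83 FPKM, and neither passed. The list was not higher in each library labelled cKO. Its mean relative to the 6 libraries was 0.51, -0.12 and 0.40 in cKO 1, 2 and 3 and -0.16, -0.09 and -0.54 in WT 1, 2 and 3.

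Helper cytokines and lineage factors were higher as a group, with 11 of 12 tested members above 0 and a median log2 difference of 0.40 (limma camera, adjusted p = 9.75e-04, and adjusted p = 0.187 with an estimated correlation). None passed over all genes or adjusted over the list alone, and 3 of the 12 also belong to the effector Treg list. Il4 stood at 5.22 ± 1.38 against 1.94 ± 1.21 FPKM, and Ifng at 4.46 ± 0.108 against 2.37 ± 1.12 FPKM, with 2 to 14 fragments behind each Il4 value. The list's call ended without cKO replicate 1 (0.0631), where its median was 0.22, and the median was 0.26 with a pseudocount of 5. The list of chemokine receptors and tissue homing did not pass (limma camera, adjusted p = 0.160), but passed upward without cKO replicate 2 (0.0198) and without WT replicate 2 (0.0366), with adjusted p = 0.616 and adjusted p = 0.629 with an estimated correlation. It had 3 of 19 members higher adjusted over the list alone and none over all genes. These were Ccr2, Cxcr3 and Cxcr6. Cxcr6, a receptor of tissue-resident lymphocytes, stood at 50.01 ± 8.43 against 23.6 ± 2.62 FPKM, a log2 difference of 1.05.

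Of the marker lists of other cells, those of myeloid and of erythroid and platelet cells passed upward at the preset correlation, the latter on erythroid members alone. Myeloid markers had a median log2 difference of 0.45 with 10 of 11 members above 0 (limma camera, adjusted p = 0.00831, and adjusted p = 0.494 with an estimated correlation). Lyz2 stood at 74.8 ± 9.36 against 52.5 ± 18.0 FPKM. Ly6g was listed at 3.77, 2.71 and 0 FPKM in cKO 1, 2 and 3 and at 0 in each library labelled WT. The myeloid list's mean relative to the 6 libraries was 0.49, 0.68 and -0.31 in cKO 1, 2 and 3 and lay between -0.34 and -0.21 in those labelled WT. Its call ended without cKO replicate 1 (0.182), without cKO replicate 2 (0.196), with a minimum mean of 5 FPKM (0.0969) and with library quality weights (0.415). The 3 tested members of the erythroid and platelet list were Hba-a1, Hba-a2 and Alas2, so the main fit tested no platelet marker. These 3 had a median log2 difference of 1.36 (limma camera, adjusted p = 9.75e-04, and adjusted p = 0.264 with an estimated correlation). Of them, 2 were higher adjusted over the list alone and none over all genes. These were Hba-a2, an alpha globin with a near-identical neighbour, at 94.5 ± 34.4 against 26.9 ± 11.6 FPKM, and Alas2, an enzyme of heme synthesis in red cells, at 7.15 ± 0.812 against 2.76 ± 1.97 FPKM. The erythroid call ended with no filter on low values (0.154), where 10 members were tested at a median of 0.19. It also ended without cKO replicate 1 (0.0631), without cKO replicate 2 (0.0664) and without WT replicate 2 (0.0655), each with 4 members tested. It passed without WT replicate 3 with 4 members (0.0438), and with 3 members without cKO replicate 3 (0.00564) and without WT replicate 1 (1.48e-04). The members tested thus differed between these fits.

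No other list passed at the preset correlation, and no member of these lists passed over all genes or adjusted over the list alone. By limma camera the adjusted p was 0.488 for Treg identity, 0.310 for the AP-1 and small Maf family, 0.310 for the heme and antioxidant response, 0.722 for the T cell receptor response, 0.627 for the interferon response, 0.740 for glycolysis, 0.132 for cholesterol synthesis and 0.740 for apoptosis regulators. It was 0.740 for B cell markers, 0.740 for plasma cell markers, 0.535 for CD8 and NK cell markers, 0.732 for conventional CD4 and T follicular markers, 0.627 for mitochondrially encoded transcripts and 0.740 for heat shock and dissociation stress. Under alternatives, cholesterol synthesis passed downward with library quality weights (0.0195) and without cKO replicate 2 (0.0357), each with adjusted p = 0.366 with an estimated correlation. Mitochondrially encoded transcripts passed downward after the length and GC correction (0.0215) and without WT replicate 1 (0.0320), with adjusted p = 0.559 and adjusted p = 0.669 with an estimated correlation. The test pointed down for the interferon response although its median and mean were both 0.01, for glycolysis with a median of 0.05 and a mean of -0.02, and for mitochondrially encoded transcripts with a median of -0.01 and a mean of 0.02. Within these lists, Hmox1, a heme-degrading enzyme repressed by Bach proteins, stood at 29.9 ± 0.888 against 21.6 ± 4.47 FPKM. Gclc of the same list went the other way, at 1.61 ± 0.133 against 2.49 ± 0.633 FPKM, while 10 of the list's 13 tested members were above 0. Jun stood at 39.8 ± 5.503 against 54.0 ± 5.67 FPKM and Egr2 at 31.3 ± 0.424 against 42.1 ± 1.77 FPKM. Klrd1, a receptor of NK cells, stood at 0, 0.546 and 0.336 FPKM in cKO 1, 2 and 3 and at 3.46, 1.81 and 1.35 FPKM in WT 1, 2 and 3. Only 0 to 14 fragments lay behind each Klrd1 value by the estimated depth. Nkg7 of the same list went the other way, at 93.2 ± 12.4 against 67.1 ± 10.5 FPKM, and 3 of the list's 6 tested members were above 0. Xist lay between 5.06 and 8.51 FPKM in the 6 libraries, and Kdm5d, Uty and Eif2s3y were listed at 0 in each of them.

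**Figure D2:**
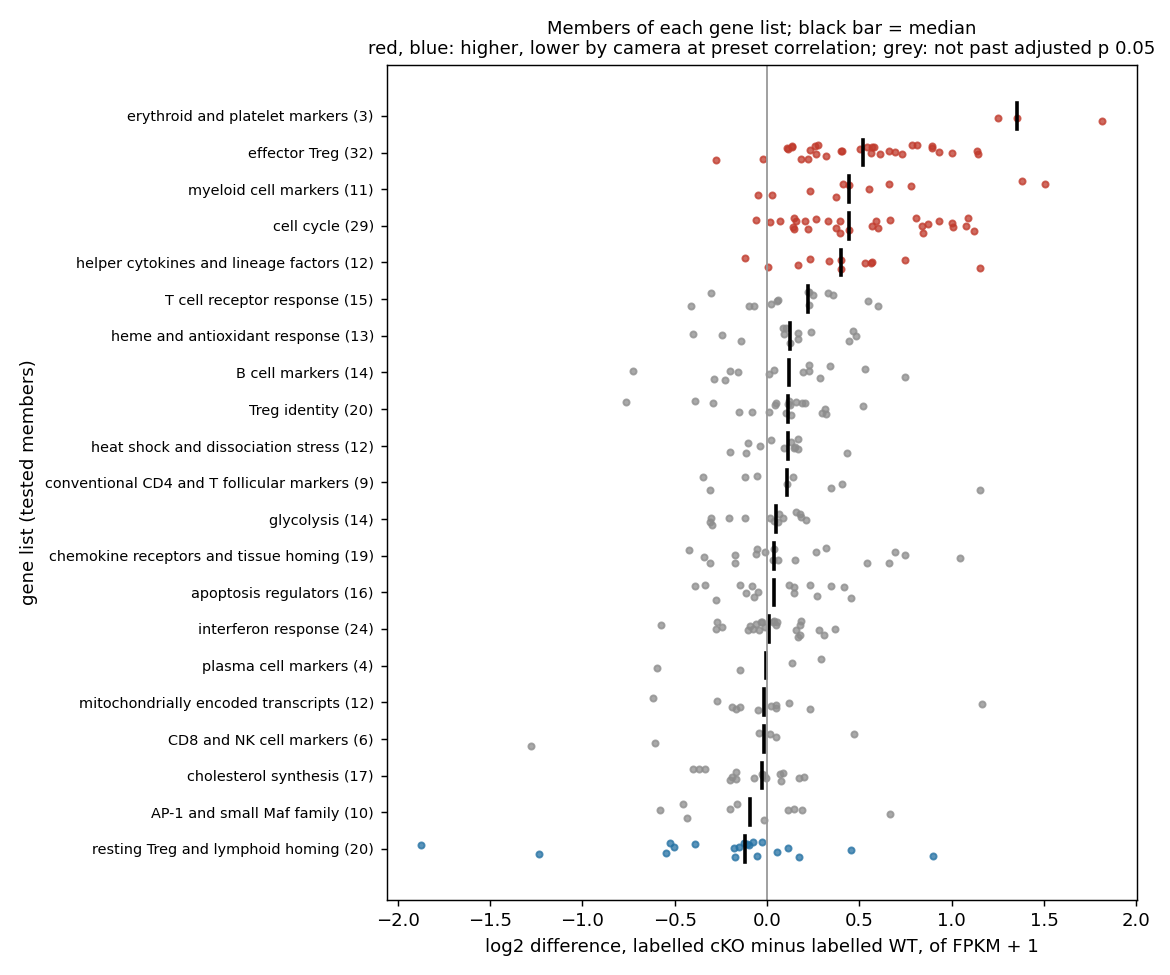
Log2 difference of FPKM + 1, labelled cKO minus labelled WT, for each tested member of 21 gene lists. Each point is a gene, the black bar is the list's median, and colour marks the lists past an adjusted p of 0.05 by camera at the preset correlation, red for higher and blue for lower. The effector Treg list has a median of 0.52 and the resting Treg list a median of -0.12.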

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

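The restriction to protein-coding genes, the length and GC correction and the alternatives for the count within the effector Treg list were chosen after the results were seen; the others were planned. Bach2 kept a positive log2 difference, from 0.26 to 0.81, and did not pass in any of the 19 alternatives. The effector Treg and cell cycle lists passed in each of them at the preset correlation. With an estimated correlation neither list passed in any of them (limma camera, adjusted p from 0.153 and from 0.366). The count of 3 genes was 1 with the replicate block and 1 among protein-coding transcripts of 300 bases or more (Igfbp4), and ranged from 5 to 15 without 1 library, with added calls that include small RNAs such as Snora17 and joining segments such as Traj43. Igfbp4 had an adjusted p of 0.300 with the block. The 17 effector Treg members higher adjusted over the list alone became 10 after quantile normalization, 11 after the length and GC correction, 0 with the replicate block, and 1 to 13 without 1 library. The resting Treg list had an adjusted p of 0.0535 with library quality weights and from 4.94e-04 to 0.126 without 1 library. The cause was not tested, beyond fewer libraries, genes or degrees of freedom in the fits that have them.

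Equal replicate numbers did not pair the libraries, with correlations of -0.06, -0.18 and -0.02 against up to 0.13, 0.10 and 0.06 for other pairs, so calls lost with the block are not read as weaker effects.

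Other results turned direction without passing on either side, except where named, and the cause was not tested. With equal sums the adjusted p was 0.947 for the interferon response, 0.940 for glycolysis and 0.985 for B cell markers. With library quality weights it was 0.957 for the interferon response, 0.870 for glycolysis, 0.701 for B cell markers and 0.377 for mitochondrially encoded transcripts, and Foxp3 differed by -0.091. It was 0.925 for conventional CD4 and T follicular markers after the length and GC correction and 0.925 for plasma cell markers among protein-coding transcripts. It was 0.990 for CD8 and NK cell markers with a minimum of 5 FPKM, where too few erythroid markers were left for a value. With no filter it was 0.718 for heat shock and 0.970 for glycolysis, and after quantile normalization 0.884 for heat shock. Without 1 library, Foxp3 ranged from -0.065 to 0.25. Adjusted p ranged from 0.218 to 0.950 for the interferon response, 0.0320 to 0.999 for mitochondrially encoded transcripts (passing downward without WT replicate 1), 0.253 to 0.844 for glycolysis, 0.547 to 0.930 for apoptosis regulators, 0.646 to 0.990 for heat shock, 0.123 to 0.879 for plasma cell markers, 0.244 to 0.855 for CD8 and NK cell markers, 0.328 to 0.930 for the T cell receptor response and 0.129 to 0.930 for B cell markers.

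With 3 libraries a group, 16.8% of simulated 2-fold changes were recovered, so most changes of that size were not detectable one gene at a time.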

Other observations

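The fits that leave out 1 library and the Bach2 interval were planned. The gene families, the use of those planned values against explanations, and the other tests below were chosen after the results were seen. Some families repeat genes of the lists above, so they are not separate observations. S100 proteins include S100a4 and S100a6 of the effector Treg list, and centromere and kinesin genes include Cenpe and Kif11 of the cell cycle list. S100 calcium-binding proteins had a median log2 difference of 0.73 in the libraries labelled cKO, with 8 of 9 tested members above 0 (limma camera, adjusted p = 1.84e-05, and adjusted p = 0.454 with an estimated correlation). Replication-dependent histones had a median of 0.60 (1.77e-04, and adjusted p = 0.454 with an estimated correlation). Both stood highest in cKO 2. Relative to the 6 libraries, the means of S100 proteins were -0.070, 1.03 and 0.039 in cKO 1, 2 and 3 and -0.30, -0.42 and -0.28 in WT 1, 2 and 3. Those of histones were -0.11, 0.82 and 0.089 against -0.29, -0.44 and -0.071, so the groups overlapped. T cell receptor V segments had a median of 0.38 with 45 of 48 above 0 (1.84e-05, and adjusted p = 0.454 with an estimated correlation). Their means were -0.23, 0.63 and 0.35 in cKO 1, 2 and 3 and -0.27, -0.80 and 0.33 in WT 1, 2 and 3, so the groups overlapped. Cytosolic ribosomal protein genes had a median of -0.15 with 10 of 82 above 0 (3.33e-06, and adjusted p = 0.477 with an estimated correlation), and a median of 0.0077 with equal sums, where the test stayed downward relative to other genes (4.07e-05). Their means were -0.48, 0.25 and 0.014 in cKO 1, 2 and 3 and 0.017, -0.18 and 0.38 in WT 1, 2 and 3, so the groups overlapped. NADH dehydrogenase subunits (0.00199) and centromere and kinesin genes (0.0117) were higher, with adjusted p = 0.506 and adjusted p = 0.454 with an estimated correlation. The means of the NADH dehydrogenase subunits were -0.30, 0.51 and 0.10 in cKO 1, 2 and 3 and -0.080, -0.33 and 0.10 in WT 1, 2 and 3, so these groups overlapped too. Proteasome subunits passed as deposited (0.0117, and adjusted p = 0.454 with an estimated correlation) but not after the length and GC correction (0.637) or quantile normalization (0.456). T cell receptor alpha J segments did not pass as deposited (0.108) but did, upward, after the length and GC correction (0.0191), quantile normalization (0.0160) and trimmed-mean scaling (0.0256). With equal sums their test pointed down and did not pass (0.623), and as deposited they had adjusted p = 0.454 with an estimated correlation. Tubulin and actin-related genes (0.129, and adjusted p = 0.454 with an estimated correlation) passed only with equal sums (0.0284), where an estimated correlation was not run. Immunoglobulin V segments (0.514) did not pass under these scalings. Ly6a, an activation marker of lymphocytes, stood at 797 ± 87.0 against 370 ± 45.7 FPKM and did not pass over all genes (limma, adjusted p = 0.365).

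The effector Treg list was higher in the libraries labelled cKO. A length or GC bias between libraries as the whole cause is argued against by a median of 0.45 after that correction. A single library apart from the rest as the whole cause is argued against by a median from 0.46 to 0.54 whichever library was left out. In those fits the adjusted p was at most 1.70e-09 (limma camera) at the preset correlation, but from 0.153 to 0.819 with an estimated correlation. The count of members past the list adjustment fell to 1 without WT replicate 3. RNA from myeloid cells, which the Foxp3 sort should remove, stays open, since the median of the myeloid markers was 85.2% of the effector list's and passed (adjusted p = 0.494 with an estimated correlation), although with library quality weights the medians were 0.23 and 0.45 and in cKO 3 the myeloid mean of -0.31 lay within the WT range while the effector mean was 0.22. RNA from B cells, which the sort should also remove, stays open as well, since their markers did not pass at a median of 22.5% of the effector list's. Igkc stood at 3373, 2688 and 1425 FPKM in cKO 1, 2 and 3 and at 7037, 2949 and 1132 FPKM in WT 1, 2 and 3. The B cell list's means relative to the 6 libraries were 0.076, 0.054 and -0.022 in cKO 1, 2 and 3. They were 0.31, 0.034 and -0.45 in WT 1, 2 and 3, so the groups overlapped. The 10 splits of the 6 libraries are too few for a share under 0.05, with 17 members past the list adjustment in the real split, the only 1 as large, and at most 0 in the others, and a camera -log10 p of 15.7 against up to 5.35 in the others, and the estimated correlation ends the call, so a shift of Treg toward an effector state with the cKO label may be followed up only as a hypothesis.

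The cell cycle list gave a median of 0.42 after the length and GC correction and an adjusted p of at most 0.00174 whichever library was left out. With an estimated correlation it did not pass, at adjusted p = 0.516 with an estimated correlation after that correction and from 0.366 to 0.835 without 1 library. Of the 10 splits, 2 gave as small a list p, with -log10 p of 9.48 in the real split and 12.6 with cKO 1, cKO 3 and WT 1 against the rest, and the splits are too few for a share under 0.05. For the resting Treg list the real split gave 3.63 and the highest other 2.92, with 1 split as large, and the splits are again too few.

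Bach2 was not lower in the libraries labelled cKO. Loss of most Bach2 transcript over the whole gene is argued against by the lower 95% limit of -0.24, which lies above a log2 difference of -1. Libraries exchanged between the groups remain open, since the lowest difference in the other splits was -0.73 with wide intervals, and so do all labels of the groups exchanged, where the limit would be -1.27. Exons outside the floxed part that are still transcribed may also keep the value up, which was not tested because the table gives 1 value for each gene. A lack of recombination without enough tamoxifen is likewise untested.

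Calls on rows listed at 0 in a whole group form the last pattern, with 2 of the 3 genes called. A step of single fragments at low depth is a candidate explanation, since 100% of the calls made by the other splits, 30 of 30, lay on such rows. The real split called 3 genes and the highest other split 6, with 7 of the 10 splits as large, and the splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split had 643 genes, while cKO 1, WT 1 and WT 2 against the rest had 1398 and cKO 1, cKO 3 and WT 2 against the rest had 1172. For Trbj2-1 a difference of the T cell receptor repertoire of the mice cannot be told apart from such steps, as the other splits made 30 calls of this kind.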
